A study of Mus musculus with 6 samples.

How the data were processed

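RNA of 6 libraries was analysed: 3 of imDCs cultured without flow (static) and 3 of imDCs under fluid shear stress (FSS), grouped by the submitters' sample titles, which also give the replicate numbers 1 to 3. Per the labels' protocols, total RNA was purified on columns and sequenced from DNA nanoballs by combinatorial probe-anchor synthesis. The submitters' processing notes name HISAT and Bowtie2, without version or role. The quantifier, the genome build, the annotation, the selection of messenger RNA and any use of strand are not given in the sources used here. No coordinates are printed for that reason, and genes that overlap or run antisense to each other cannot be told apart with certainty.

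The authors deposited a table of 22899 genes with NCBI gene IDs and symbols, both for the whole series and per sample; the values of all 6 libraries were identical in both. Per the file headers the values are expression, with no unit. They were taken as FPKM, inferred from the deposited values. The totals differ between libraries (413898 to 470596). The sum of value times transcript length came to 0.739 to 0.831 times 1e9 with median transcript lengths and 1.04 to 1.18 times 1e9 with the longest ones. The inference rests on these sums lying near 1e9. They varied between libraries too, and FSS replicate 3 was lowest in both (0.739 and 1.04). FPKM divide by the mapped fragments of a library and by transcript length, so a few abundant genes can shift all others. In 4828 genes the values were blank in all libraries, which left 18071. Spreadsheet software had turned 26 symbols into dates, and these were matched by gene ID. Of the IDs, 21633 were found in an NCBI gene table of assembly GRCm38.p6, used here for names and for which genes are neighbours. Low values were searched for the steps that whole reads would leave and none were found, so depth per sample is unknown and no counting interval is given.

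The test fixed before the data were examined assumed counts and named limma on log2(value + 1) for files that hold FPKM, which was used. Genes at 1 FPKM or more in at least 3 libraries were kept (10899), 1 FPKM was added before log2, and limma 3.58.1 in R 4.3.3 fitted FSS minus static with moderated variances that follow the mean (trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p of a gene is from this model unless a block or another setting is named. Fold changes as ratios are of mean FPKM. Gene lists, 33 in all, were fixed before the data were examined; 29 with at least 5 tested members went through limma's camera with a preset correlation of 0.01, with an estimated correlation, and through fry, adjusted over the lists. Members past the gene test were counted over all genes and adjusted over the list alone.

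Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean log2(FPKM + 1) of 2 or more and no overlap between the groups, leaving out predicted genes and pseudogenes. It adds up to 4 members per list by smallest adjusted p (2 where none passed), and Klf2, Klf4, Piezo1, Ccr7, Cd40, Cd80, Cd86, Itgax, H2-Ab1, Actb, Tagln2 and Hmox1 whatever their result. The rule was written for log2 CPM and applied to log2(FPKM + 1). Other genes are said to have been taken up after their values were seen, and 1 gene that the rule names is not reported here.

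Both groups carry the replicate numbers 1 to 3 in their labels, which do not say what a number shares. Deviations from the group means correlated across genes between the libraries of one number (Pearson 0.79, 0.66 and 0.87 for numbers 1, 2 and 3). Between static replicate 1 and FSS replicate 2 the correlation was 0.22, and between static replicate 2 and FSS replicate 1 it was 0.28. Number 3 against numbers 1 and 2 of the other group gave -0.78 to -0.54. The numbers were therefore taken to pair the samples, and a fit with the number as a block was run beside the other one. The differences of the pairs correlated across genes at 0.87, 0.78 and 0.74.

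The model was tested on simulated data for FSS against static, with 10899 genes, 50 of them changed by each of 4 fold sizes. Without the block it recovered 0% of genes changed 1.5-fold, 24% at 2-fold, 90% at 4-fold and 98% at 8-fold, with 0 false calls; with the block it recovered 32%, 72%, 98% and 96%, with 1 false call. With no change simulated, neither fit made a call. Each simulated library carried the replicate-number effect seen in these data plus independent noise at the spread within pairs. The gain from the block therefore follows from that assumed pairing and does not test it. The noise was drawn for each gene on its own, so a shift of many genes in 1 library was not simulated. False calls from such a shift would not show. The alternatives were a pseudocount of 0.1, no filter, a threshold of 0.01, the replicate block, and each library left out in turn. Median-ratio scaling, equal totals, the block with median-ratio scaling, a mean of 5 FPKM or more, and leaving out pair 3 with and without the block were added after seeing the data. Transcript lengths, 3' UTRs and repeat matches (blastn 2.17.0, at least 80% identity over 60 bases) came from reference transcripts, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.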

Results

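The RNA of mouse immature dendritic cells (imDCs), sentinel cells that take up antigen before they mature into presenters of it to T cells, was measured with and without fluid shear stress (FSS). Marrow of male C57BL/6 mice aged 7 weeks had been cultured for 7 days with GM-CSF (20 ng/ml) and IL-4 (10 ng/ml) and the cells selected by CD11c, an integrin subunit that marks dendritic cells. A cone-plate device, which turns a cone over the dish so that the medium drags on the cells, applied 10 dyn/cm2 for 3 h, a load chosen within the range of flow in veins. Static cultures were the controls. Each group held 3 libraries, numbered 1 to 3 in both groups. The comparison asks which messenger RNAs differ between loaded and static imDCs.

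Between 10390 genes (FSS replicate 3) and 10959 genes (FSS replicate 2) reached 1 FPKM (fragments mapped to a gene, divided by transcript length and by all mapped fragments). The summed FPKM of a library ran from 413898 in FSS replicate 1 to 470596 in static replicate 3. Sequencing depth is unknown, because the values carry no read counts, so no counting error can be attached to a gene. Nothing in the labels says that the replicates came from separate cultures or animals, and p-values here measure only the spread between these samples, which may be technical. The first principal component held 48.5% of the variance and set both libraries numbered 3 apart from the other 4, while the second held 36.6% and separated FSS from static. With the group in the model, 4684 of the 10899 genes tested differed between replicate number 3 and numbers 1 and 2 (limma, Benjamini-Hochberg), 1496 of them higher and 3188 lower in number 3.

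**Figure D1:**
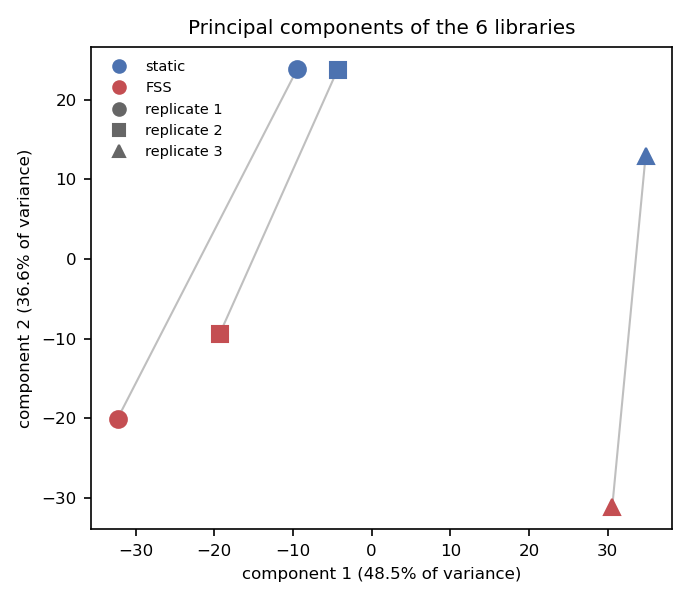
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), with blue for static, red for FSS, a symbol for each replicate number and a line joining the libraries of one number. Both libraries numbered 3 lie to the right on component 1 (48.5% of the variance), and the FSS library lies below its static partner on component 2 (36.6%) in all 3 pairs.

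Heat shock genes were among the largest rises under FSS. Hspa1b and Hspa1a, which encode the stress-inducible HSP70 chaperone, went from 12.4 ± 8.37 to 973 ± 316 FPKM and from 14.5 ± 10.4 to 1107 ± 395 FPKM (mean ± SD, n = 3 per group). Gdf15, a stress-induced cytokine of the TGF-beta family, rose 9.61-fold, and Icosl, the ligand of the T-cell costimulator ICOS, rose 4.38-fold. Edn1, which encodes the vasoconstrictor endothelin-1, fell from 141 ± 36.9 to 16.8 ± 4.8 FPKM. Irf4, a transcription factor of dendritic cell subsets, the chemokine gene Ccl3 and the growth regulator Myc fell as well. Over 10899 genes, limma on log2(FPKM + 1) placed 93 genes higher and 94 lower at a Benjamini-Hochberg adjusted p under 0.05, and 85 and 53 of them changed 2-fold or more.

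The replicate numbers were taken to pair the samples, a reading drawn from these same data and not stated in the labels. With the number as a block the same test placed 842 genes higher and 2739 lower (161 and 110 by 2-fold or more). All 187 calls made without the block were kept. Without the block, the number of calls changed when any 1 library was left out. It was 3 higher and 0 lower without static replicate 1, 14 and 4 without static replicate 2, and 27 and 7 without static replicate 3. Without FSS replicate 1 it was 3 and 1, without FSS replicate 2 also 3 and 1, and without FSS replicate 3 it was 254 and 161. At an unadjusted limma p under 0.05 these fits gave 1230 to 2567 genes, against 1969 with all libraries. Hspa1b and Hspa1a passed in each of those 6 fits, and of the 41 genes named by rule that passed with all libraries, 3 passed without static replicate 1 (Hspb1 being the other). The median gene stood 0.12 log2 lower under FSS, and 0.03 higher once libraries were scaled by their median ratio. With that scaling 154 genes were higher and 69 lower, with totals made equal 68 and 45, and with the scaling and the block together 2129 and 1772, so the balance of rises and falls depends on the scaling. For each gene list, counts with the block are followed by those with the block and median-ratio scaling, marked as scaled. The groups did not overlap for 2777 genes, 25.5% of those tested. The chance share of 10% holds for 6 exchangeable libraries, and samples taken as paired are not exchangeable.

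**Figure D2:**
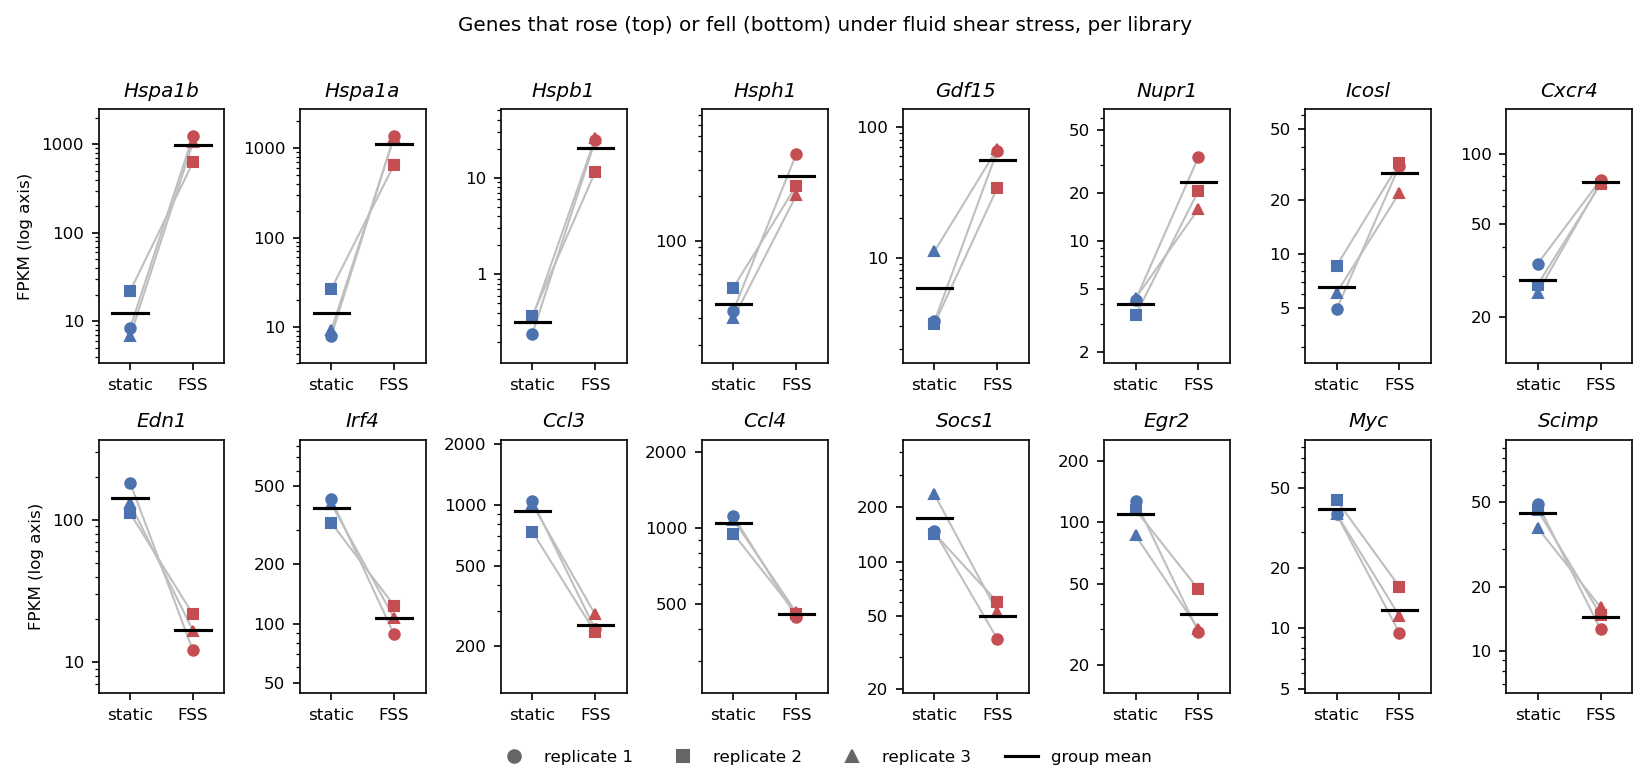
FPKM per library on a log axis for 8 genes that rose and 8 that fell, in blue for static and red for FSS, with a symbol for each replicate number, a grey line joining the libraries of one number and a black bar at the group mean. Hspa1b rises from a mean of 12.4 to 973 FPKM and Edn1 falls from 141 to 16.8 FPKM, and the groups do not overlap for any of the 16 genes.

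Of the 20 heat shock genes fixed before the data were examined, 14 rose, none fell and 6 did not pass (18 rose when adjusted over the list alone, 18 with the replicate block, and 18 scaled). The list median was 1.28 on the log2(FPKM + 1) scale, a scale that understates the change of genes with low values. Hspb1, the small heat shock protein HSP27, rose from 0.32 ± 0.07 to 20.5 ± 7.8 FPKM (log2 difference 3.95 ± 0.29, SE; limma adjusted p = 0.00402). For Hspa1b the log2 difference was 6.30 ± 0.43 (gene ID 15511) and for Hspa1a 6.28 ± 0.46 (gene ID 193740), each with an adjusted p of 0.00402. The reads of this pair of nearly identical genes can be divided between them only uncertainly. Hsph1, the nucleotide exchange factor HSP110, rose 7.26-fold and its relative Hspa4l 4.69-fold. Hsf1, the factor that drives the heat shock response and taken up after its values were seen, gave 13.7 ± 2.11 and 12.2 ± 1.89 FPKM and did not pass (limma adjusted p = 0.753); its direction turns with median-ratio scaling. The list stood above other genes by camera (adjusted p = 5.95e-29), though with adjusted p = 0.416 with an estimated correlation. In each pair the list median was above 1: 1.73, 1.09 and 1.19.

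Some genes of the integrated stress response rose as well. Of 22 tested members of the list for endoplasmic reticulum stress and the integrated stress response, 4 rose and none fell (6 and 0 adjusted over the list alone; 10 and 1 with the block; 12 and 1 scaled). Chac1, which degrades glutathione, rose from 0.187 ± 0.0945 to 5.07 ± 1.25 FPKM (limma adjusted p = 0.00653). Ddit3, encoding the factor CHOP, rose 2.15-fold, and Ddit4, an inhibitor of mTORC1 signalling, 2.51-fold. Trib3, a pseudokinase that acts downstream of CHOP, rose 6.24-fold, from 1.08 ± 1.13 to 6.74 ± 2.56 FPKM (limma adjusted p = 0.0496). Gdf15 and Nupr1, a stress-responsive transcriptional regulator that went from 4.0 ± 0.52 to 23.5 ± 9.23 FPKM, were outside the list. Of 28 tested genes of hypoxia and glycolysis, 3 rose: Adm, the peptide hormone adrenomedullin (3.85-fold), P4ha1, a collagen prolyl hydroxylase (2.36-fold), and Ero1l, an oxidase of the endoplasmic reticulum (2.87-fold). Adm was low, at 0.607 ± 0.0808 and 2.33 ± 0.327 FPKM (log2 difference 1.05). It passed in 0 of the 6 fits with 1 library left out. None of the 28 fell, and 8 rose and 1 fell when adjusted over the list alone, against 12 and 1 with the block and 17 and 1 scaled. Adm, P4ha1 and Ero1l are not enzymes of glycolysis. Camera placed both lists above other genes (adjusted p = 1.82e-06 and 2.13e-08), and neither held: adjusted p = 0.933 with an estimated correlation for the first and 0.96 for the second.

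Inflammatory genes moved in both directions. Of 26 genes of the NF-kB pathway, 2 rose and none fell (6 and 0 adjusted over the list alone; 9 and 0 with the block; 13 and 0 scaled). They were Bcl3, a nuclear cofactor of NF-kB (16.5 ± 2.88 to 49.9 ± 6.94 FPKM), and Irak2, a kinase of toll-like receptor signalling (34.5 ± 3.73 to 97.9 ± 23.5 FPKM), with limma adjusted p-values of 0.018 and 0.0304. Icam1, an adhesion molecule and NF-kB target, stood at 88.0 and 170 FPKM and passed with the block alone (limma adjusted p = 0.0545 without and 0.00191 with it). Camera gave the list an adjusted p of 1.82e-06, but adjusted p = 0.96 with an estimated correlation. Its median was 0.31, 0.30 and -0.09 log2 in pairs 1 to 3. The mean of the libraries numbered 3 was lower in this list, by a median of 0.46 log2. Of 37 cytokine and chemokine genes, 3 fell and none rose (7 and 5 adjusted over the list alone; 16 and 8 with the block; 14 and 12 scaled). Ccl3 and Ccl4, which attract monocytes and T cells, fell from 929 ± 168 to 255 ± 28.4 FPKM and from 1048 ± 86.8 to 457 ± 9.85 FPKM. Ccl24, an attractant of eosinophils, fell from a mean of 1209 to 501 FPKM (log2 difference -1.30 ± 0.23, SE). With the block Vegfa and Cxcl10 rose, at 17.4 and 41.6 FPKM and at 81.6 and 260 FPKM (limma adjusted p = 0.00304 and 0.000623, against 0.0524 and 0.08 without it).

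Chemotaxis receptors split in the same way. Of 18 tested, 3 rose and 3 fell (4 and 5 adjusted over the list alone; 4 and 12 with the block; 5 and 7 scaled). Cxcr4, the receptor of CXCL12, rose from 29.0 ± 4.34 to 75.6 ± 1.6 FPKM (limma adjusted p = 0.0167), and Ccrl2, a receptor that binds chemerin without signalling, rose 4.25-fold. Ptger2, a prostaglandin E2 receptor taken up after its values were seen, rose 3.17-fold. Among the falls, Ccr1 went from 80.4 ± 12.7 to 33.0 ± 5.41 FPKM and Ccr2 from 68.3 ± 21.1 to 24.1 ± 3.6 FPKM. Ccr7, which guides mature dendritic cells to lymph nodes, stood at 261 ± 91.3 and 168 ± 53.3 FPKM; it was lower in all 3 pairs and passed only with the block (limma adjusted p = 0.34 without and 0.0091 with it).

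The genes of dendritic cell maturation did not move as a group. Of 28 tested, 2 rose and none fell (2 and 4 adjusted over the list alone), while with the block 2 rose and 11 fell (scaled, 4 and 10). The rises were in the costimulatory ligands Icosl (6.53 ± 1.9 to 28.6 ± 5.65 FPKM, limma adjusted p = 0.0156) and Tnfsf9, the ligand of 4-1BB (4.32 ± 0.297 to 10.7 ± 1.93 FPKM, adjusted p = 0.0336). The classical costimulators Cd40, Cd80 and Cd86 gave log2 differences of -0.50, -0.16 and -0.48, and their adjusted p-values were 0.524, 0.85 and 0.649 without the block; Cd40 and Cd86 fell with it (0.0122 and 0.0199). The mean of the libraries numbered 3 was lower in this list, by a median of 0.62 log2 against numbers 1 and 2. Of 17 tested genes of conventional dendritic cell identity, 1 fell and none rose (1 and 0 adjusted over the list alone; 8 and 0 with the block; 3 and 1 scaled). It was Irf4, from 388 ± 55.0 to 106 ± 17.6 FPKM (log2 difference -1.86 ± 0.20, SE; limma adjusted p = 0.0133). Itgax, which encodes CD11c, stood at 537 ± 54.3 and 448 ± 52.6 FPKM (adjusted p = 0.475; 0.0199 with the block, and 0.514 with the block and median-ratio scaling). None of 15 genes of MHC class II presentation passed, also adjusted over the list alone, and H2-Ab1 gave 1035 ± 75.6 and 1096 ± 129 FPKM. With the block 1 of them, the ubiquitin ligase gene Marchf1, fell (limma adjusted p = 0.00186 against 0.255); scaled, 2 rose and 1 fell. Of 16 genes of class I presentation none passed, none when adjusted over the list alone, and 8 fell with the block, but scaled 1 rose and 2 fell.

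**Figure D3:**
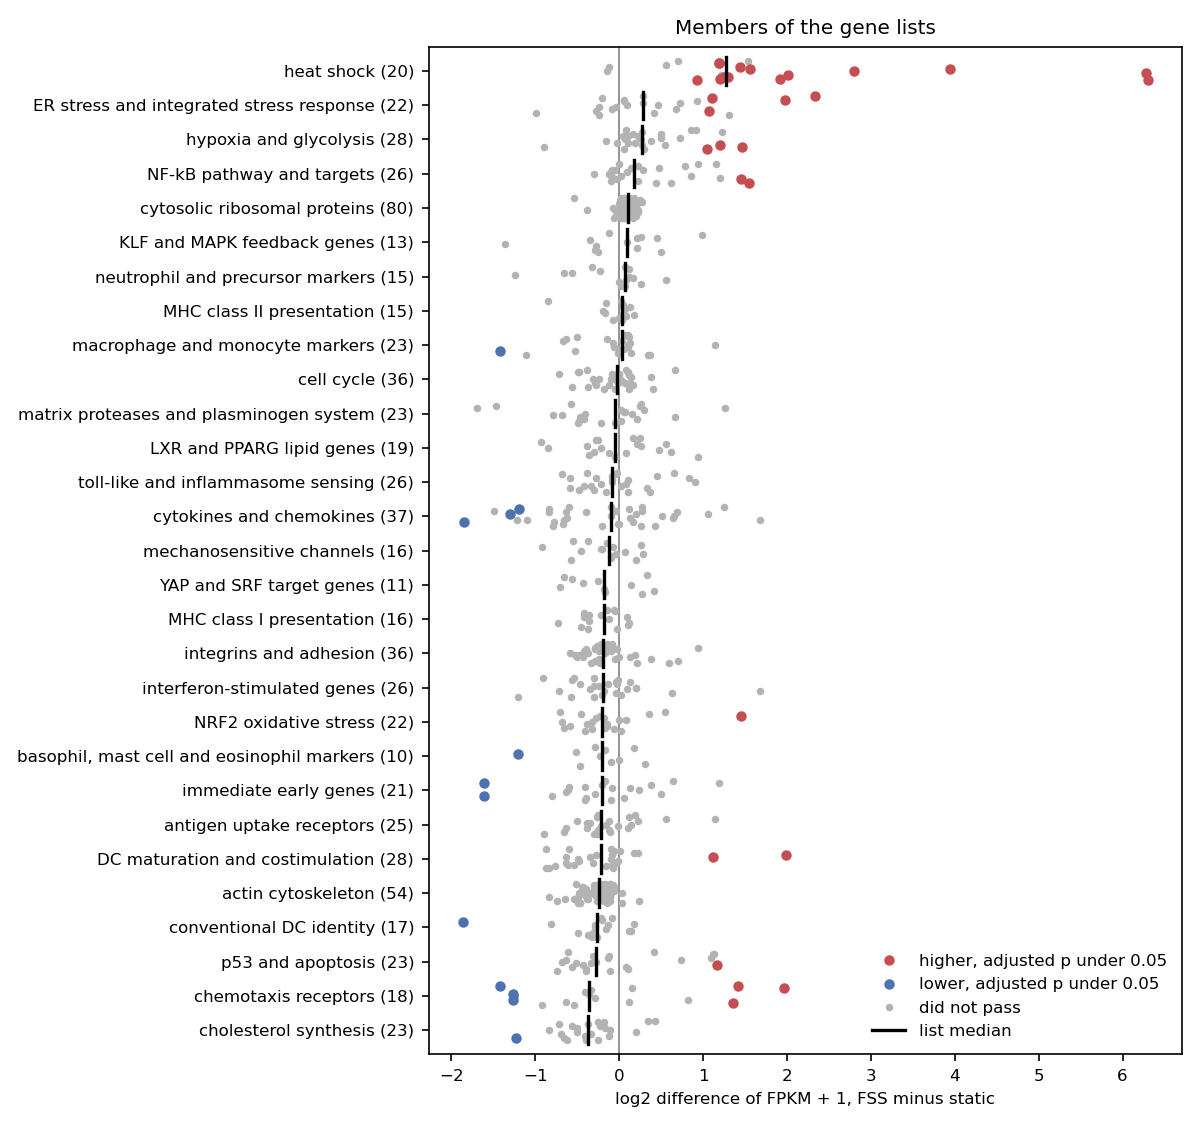
Log2 difference of FPKM + 1, FSS minus static, for each tested member of 29 gene lists, with the number of tested members in brackets, red and blue points for members higher or lower at a limma adjusted p under 0.05, grey for the rest and a black bar at each list's median. The heat shock list has its median at 1.28 and 14 red points, and every other list median lies between -0.37 and 0.28; the median of all genes was -0.12.

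Genes tied to mechanical load showed few calls. Of 54 actin cytoskeleton genes none passed, nor when adjusted over the list alone, and 27 fell with the block (scaled, 12 fell and 1 rose). Actb stood at 8073 ± 636 and 5868 ± 1033 FPKM (limma adjusted p = 0.202; 0.00339 with the block; 0.157 with the block and the scaling), and Tagln2 gave adjusted p-values of 0.852 and 0.0999. Camera placed the list below other genes (adjusted p = 0.0102), a call lost with an estimated correlation (adjusted p = 0.96 with an estimated correlation), without FSS replicate 1 (adjusted p = 0.107) and with median-ratio scaling (adjusted p = 0.067). The camera call was kept with the block (adjusted p = 0.000136) and with the block and the scaling (adjusted p = 0.0344). It was lost with the block and an estimated correlation (camera adjusted p = 0.976). Of 16 tested mechanosensitive channel genes none passed, also over the list alone, and 5 fell with the block (scaled, 3 rose and 4 fell). Piezo1, a stretch-activated channel, gave a log2 difference of -0.21 ± 0.20 (SE; limma adjusted p = 0.658). Klf2, a factor that flow induces in endothelium, gave a log2 difference of 0.99 ± 0.32 (SE) and rose with the block alone (adjusted p = 0.164 without and 0.00444 with it), whereas Klf4 gave 10.0 and 10.5 FPKM (adjusted p = 0.924). In their list of 13 KLF and MAPK feedback genes none passed (0 higher and 1 lower adjusted over the list alone), and with the block 2 rose and 2 fell (scaled, 6 and 1). Of 11 tested YAP and SRF targets none passed, also over the list alone, and with the block 1 rose and 5 fell (scaled, 3 and 3). Of 36 integrin and adhesion genes none passed, 1 was higher adjusted over the list alone, and 4 rose and 12 fell with the block, a balance that turns when scaled (7 and 5). Among 21 immediate early genes, Myc fell from 39.1 ± 3.71 to 12.3 ± 3.38 FPKM and Egr2 from 110 ± 20.9 to 35.5 ± 10.1 FPKM, and none rose (3 rose and 5 fell adjusted over the list alone; 4 and 9 with the block; 6 and 6 scaled).

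Among lipid genes few passed. Of 23 tested genes of cholesterol synthesis, 1 fell and none rose (2 and 0 adjusted over the list alone; 13 fell and 2 rose with the block; 9 and 2 scaled), with a list median of -0.37 log2 and of -0.20 after median-ratio scaling. The gene was Hsd17b7, a reductase of the pathway, from 7.04 ± 0.946 to 2.45 ± 0.625 FPKM (limma adjusted p = 0.0337). Hmgcs1, the synthase that precedes HMG-CoA reductase, stood at 44.4 ± 4.72 and 24.4 ± 1.97 FPKM (adjusted p = 0.0522, and 0.00177 with the block). The camera call for this list (adjusted p = 0.0182) was lost with an estimated correlation (adjusted p = 0.96 with an estimated correlation), without static replicate 3 (0.0649) and without FSS replicate 1 (0.107). None of 19 LXR and PPARG lipid genes passed, 1 was lower adjusted over the list alone, and 4 rose and 5 fell with the block, which turns when scaled (8 and 2); Lpl, lipoprotein lipase, stood at 655 ± 89.6 and 342 ± 53.1 FPKM (limma adjusted p = 0.0551, and 0.000643 with the block). Of 22 NRF2 genes only Hmox1, the haem-degrading enzyme, rose, from 340 ± 102 to 906 ± 104 FPKM (adjusted p = 0.0383); 1 rose and 1 fell adjusted over the list alone, and 3 rose and 8 fell with the block (scaled, 3 and 5). Of 23 p53 and apoptosis genes, Gadd45a, a growth arrest gene, rose 2.44-fold and none fell (4 rose and 1 fell adjusted over the list alone; 5 rose and 10 fell with the block; 7 and 7 scaled).

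In lists of sensing and uptake no gene passed without the block. Of 26 toll-like receptor and inflammasome genes, 1 was higher adjusted over the list alone, and 3 rose and 7 fell with the block, which turns when scaled (6 and 5), with Tlr2 at 39.2 ± 6.48 and 74.2 ± 12.2 FPKM (limma adjusted p = 0.0676, and 0.00311 with the block). Of 25 antigen uptake receptors, 1 was lower adjusted over the list alone, and 2 rose and 11 fell with the block, but 4 and 4 scaled, with the beta-glucan receptor gene Clec7a at means of 478 and 255 FPKM (adjusted p = 0.0614, and 0.00148 with the block). Of 26 interferon-stimulated genes, 1 was higher and 2 lower adjusted over the list alone, and 1 rose and 7 fell with the block (scaled, 2 and 6). The mean of the libraries numbered 3 was lower in the toll-like and interferon lists, by medians of 0.45 and 0.53 log2. In pairs 1 to 3 the toll-like medians were -0.03, 0.003 and -0.29 log2, and the interferon medians -0.11, 0.08 and -0.58. Of 23 genes of matrix proteases and the plasminogen system none passed over the list alone, and 4 rose and 10 fell with the block, but 7 and 7 scaled, with the urokinase receptor gene Plaur at 332 ± 97.4 and 126 ± 64.8 FPKM (limma adjusted p = 0.09, and 0.000865 with the block).

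Markers of other cell types that a CD11c-selected marrow culture could hold were compared as well. Of 23 macrophage and monocyte markers 1 fell, the monocyte receptor gene Ccr2, and none rose (1 and 0 adjusted over the list alone; 4 rose and 6 fell with the block; 6 and 5 scaled). Of 15 neutrophil and precursor markers none passed, also over the list alone, and 1 rose and 3 fell with the block, which turns when scaled (5 and 2). In that list the mean of the libraries numbered 3 was higher, by a median of 0.40 log2. Of 10 basophil, mast cell and eosinophil markers 1 fell, Il1rl1, the IL-33 receptor, from 3.48 ± 0.71 to 0.943 ± 0.304 FPKM (limma adjusted p = 0.035; 1 also over the list alone; 1 rose and 3 fell with the block; 2 and 2 scaled). The lists of B and plasmacytoid cells, of T and NK cells, and of erythroid, platelet and stromal cells had fewer than 5 tested members and were not tested as groups, and no mitochondrially encoded gene was listed. Of their members named by rule none passed without the block. With it the granzyme genes Gzmb (5.96 ± 2.61 and 2.46 ± 1.64 FPKM) and Gzma (6.8 ± 3.57 and 3.48 ± 2.21 FPKM) fell (limma adjusted p = 0.00352 and 0.00371). Kdr, a VEGF receptor, rose with it from a low 0.78 to 1.23 FPKM (adjusted p = 0.04), while Spib, Cd79b and Pf4 gave 0.24, 0.385 and 0.0882. With median-ratio scaling added Spib and Pf4 rose too (adjusted p = 0.0485 and 0.0145). Of 36 cell cycle genes none passed, also over the list alone, and 2 rose and 8 fell with the block, which turns when scaled (9 and 4). In the cell cycle list the mean of the libraries numbered 3 stood higher, by a median of 0.51 log2. Camera gave this list an adjusted p of 0.59, and it was called without static replicate 3 (adjusted p = 0.0462) and without FSS replicate 1 (adjusted p = 0.000398). Of 80 genes of cytosolic ribosomal proteins none passed, also over the list alone, and 7 rose and 2 fell with the block (scaled, 23 and 1). For these genes the mean of the libraries numbered 3 was higher, by a median of 0.36 log2. The median difference of these genes under FSS was 0.11 log2, and 0.28 after median-ratio scaling. Camera placed them above other genes (adjusted p = 2.49e-05), a call lost with an estimated correlation (adjusted p = 0.96 with an estimated correlation) and without FSS replicate 3 (adjusted p = 0.86).

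Camera thus called 7 of the 29 lists tested, and the other 22 had adjusted p-values from 0.187 to 0.949. None of the 7 held with an estimated correlation, and fry, which asks whether a list moves one way without reference to other genes, called heat shock alone (adjusted p = 0.0254). Other splits of the 6 libraries gave between 5 and 15 such calls. For cytokines, LXR and PPARG lipid genes, p53 and apoptosis, toll-like and inflammasome sensing, and cell cycle, the median and the mean lay below 0 while the direction of the camera test was upward; for MHC class II, macrophage and neutrophil lists the mean alone lay below 0.

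Among the single genes with the largest rises, Ccdc114, a component of ciliary dynein docking, went from 3.21 ± 1.44 to 38.3 ± 13.1 FPKM and Dlgap1, a synaptic scaffold gene, from 1.58 ± 0.505 to 23.6 ± 10.7 FPKM (limma adjusted p = 0.0133 for both). Among the largest falls were Socs1, a suppressor of cytokine signalling (3.48-fold lower), Slfn1 (3.27-fold), Tnfaip8l3 (3.59-fold), Itpripl1 (4.39-fold) and Scimp, an adaptor of toll-like receptor signalling (3.05-fold).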

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

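The scalings, the filter at a mean of 5 FPKM and the omission of pair 3 were chosen after seeing the data. Counts are given as genes higher, lower, higher by 2-fold and lower by 2-fold, against 93, 94, 85 and 53. With the replicate block they were 842, 2739, 161 and 110; with the block and median-ratio scaling 2129, 1772 and 217 (65 lower by 2-fold); with the block and pair 3 left out 1526, 2608, 200 and 96. With pair 3 left out and no block they were 371, 356 and 175 (73 lower by 2-fold). Without the filter they fell to 14, 7, 13 and 6, with more genes tested (17202); at a mean of 5 FPKM to 40, 45, 39 and 33. Median-ratio scaling gave 154 higher, 128 by 2-fold and 27 lower by 2-fold, and equal totals 45 and 34 lower. At a threshold of 0.01, 4 and 1 were left. Leaving out 1 library gave 3 to 254 higher, 0 to 161 lower, 3 to 184 and 0 to 81 by 2-fold. The cause of these differences was not tested.

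With an estimated correlation 0 of 7 lists were called, and by fry 1. The adjusted p with an estimated correlation was 0.416 for heat shock, 0.933 for the integrated stress response and 0.96 for hypoxia, NF-kB, actin, cholesterol synthesis and ribosomal proteins. By fry it was 0.213 for hypoxia, 0.139 for the integrated stress response, 0.336 for NF-kB, 0.0985 for actin and for cholesterol synthesis and 0.813 for ribosomal proteins. Actin was at 0.067 with median-ratio scaling and cholesterol synthesis at 0.089 with the mean filter. Leaving out 1 library moved actin from 0.00267 to 0.107, cholesterol synthesis from 0.00792 to 0.107 and ribosomal proteins from 1.98e-11 to 0.86. The cause was not tested.

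For the 111 named genes 1310 values kept their direction and side of the 0.05 threshold over all alternatives, 209 came past it, 211 no longer passed and 14 turned direction, in 7 genes. The 1310 include all 111 genes at the threshold of 0.01, where the fit is the same. Over all genes only 4 higher and 1 lower pass 0.01, so most of the 41 named calls are lost there and are missing from the 211. None of the 14 turned values passed, nor did their genes with all libraries and no block or scaling. Cd80 was at 0.003994 log2 and Tagln2 at 0.002472 with median-ratio scaling, with or without the block, and Piezo1 at 0.02783 with pair 3 left out, with or without the block. Leaving out 1 library ran from -0.3867 to 0.1291 for Cd80, -0.4433 to 0.07722 for Tagln2, -0.1554 to 0.3648 for Klf4, -0.134 to 0.7566 for Prss34, -0.03966 to 0.338 for Spib and -0.3845 to 0.07374 for Cd79b. The block brought 61 of them past it, ended none of their 41 calls and changed no call of a list. Alternatives that need counts (RLE factors, total counts, DESeq2, voom) were not run, since the values are FPKM. The planned filter at a CPM of 1 in 3 libraries has no counts to rest on either, and 1 FPKM in 3 libraries stood in for it. Depth is unknown.

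Of the lists not called, 16 turned direction under some alternative, 44 times in all, and none of these values passed. By fry, which does not compare with other genes, the adjusted p was 0.847 for MHC class II, p53, toll-like sensing, macrophage and neutrophil lists, 0.36 for cytokines, 0.304 for LXR and PPARG and 0.918 for cell cycle. Cytokines turned at 0.941 with median-ratio scaling, 0.782 with the block and that scaling, 0.494 at a mean of 5 FPKM, 0.79 with pair 3 left out and 0.733 with the block as well. With pair 3 left out, without and with the block, mechanosensitive channels were at 0.816 and 0.834 and interferon-stimulated genes at 0.79 and 0.484. The p53 list was at 0.973 without the filter and 0.954 with the block and median-ratio scaling, neutrophil markers at 0.941 with that scaling and matrix proteases at 0.94 with the block. Leaving out 1 library ran from 0.129 to 0.862 for dendritic cell maturation, 0.129 to 0.976 for MHC class II, 0.196 to 0.978 for NRF2, 0.598 to 0.877 for antigen uptake, 0.000398 to 0.86 for cell cycle, 0.596 to 0.937 for chemotaxis receptors, 0.288 to 0.966 for cytokines, 0.502 to 0.957 for integrins, 0.0599 to 0.768 for interferon-stimulated genes, 0.0986 to 0.993 for macrophage, 0.129 to 0.875 for neutrophil and 0.435 to 0.912 for matrix protease lists. The cause was not tested.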

Other observations

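Gene families outside the fixed lists were grouped by symbol after their values were seen, so their tests describe these samples alone. Of 10 tested genes of SR proteins, which guide splicing, 3 fell and none rose, and 8 fell with the replicate block (7 with the block and median-ratio scaling). Srsf5 fell from 76.7 ± 10.2 to 31.6 ± 4.66 FPKM (limma adjusted p = 0.0287), Srsf6 from 57.0 ± 5.93 to 25.8 ± 3.88 FPKM and Srsf2 from 91.6 ± 9.09 to 48.6 ± 5.31 FPKM. The family median was -0.69 log2, and -0.52 with median-ratio scaling; camera gave p = 3.74e-05, and p = 0.0567 with an estimated correlation. Of 43 ribosome biogenesis factors 5 fell and none rose, and 23 fell with the block (20 fell and 1 rose with the block and median-ratio scaling). The 5 were Nol9, a kinase of ribosomal RNA processing, Tsr1, Nol10, Nop56 and Polr1b, a subunit of RNA polymerase I, with log2 differences of -1.52, -1.05, -0.98, -0.99 and -0.92. The family median was -0.30 log2, and -0.14 with median-ratio scaling (camera p = 9.76e-07, and p = 0.0787 with an estimated correlation). Of 62 replication histone genes none passed by limma without the block and 48 fell with it (camera p = 0.0026, and p = 0.637 with an estimated correlation). With the block and median-ratio scaling 42 fell and 1 rose. Some of these genes had nearly the same values, such as Hist1h2bq (37.73 and 22.75 FPKM, static and FSS) and Hist1h2br (37.71 and 22.80 FPKM). The 48 need not be separate observations.

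Single genes picked out after their values were seen include Ifnb1, which encodes interferon beta and rose from 0.26 ± 0.2 to 2.36 ± 0.291 FPKM (limma adjusted p = 0.0156), although 0 of 26 interferon-stimulated genes passed without the block. Smad3, a mediator of TGF-beta signalling, rose 7.57-fold (adjusted p = 0.0133), and Fam3b, a secreted cytokine-like protein gene, fell from 11.5 ± 6.52 to 0.127 ± 0.0503 FPKM (adjusted p = 0.0147). Among the most abundant genes were Col19a1, a collagen gene, at 3476 and 4889 FPKM (rank 9) and Tep1 at 2596 and 3012 FPKM (rank 11), static and FSS. Neither rose in all pairs: Col19a1 stood at 3566 and 3541 FPKM in pair 2, and Tep1 at 2807 and 2450 FPKM in pair 3. The annotation and quantifier are not given, so which reads these values count could not be checked.

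Tests chosen only after the result was seen were that of scaling for the heat shock genes, the splits for the 4 gene counts and those of the families above. The higher heat shock genes were set against scaling, warmth and loss of water. The lowest mean over the 3 pairs of the list median was 1.335 log2 over 3 scalings, which argues against scaling as the whole cause. Cirbp and Rbm3, known to fall when cells are warmed, gave a mean of -0.2595 log2 (SE 0.063), where only Rbm3 passed with the block (limma adjusted p = 0.0201, and 0.193 with median-ratio scaling added), so a warmer culture on the device cannot be told apart from shear. For loss of water from the medium, 1 of 6 osmotic stress genes tested rose with the block (Slc38a2). Slc5a3, an osmolyte transporter noticed afterwards, rose with it from 3.04 to 16.9 FPKM, as water loss would give (limma adjusted p = 0.000643, and 0.0659 without the block). The rule fixed before set bounds against water loss for Akr1b3 and Slc6a6, and these were met unscaled (0.25 and -0.063 log2, limit 0.26). With median-ratio scaling, which was not part of that rule, Akr1b3 reached 0.429, so the bound was not used. Reads shared by Hspa1a and Hspa1b leave their split uncertain, and shear itself stays open with warmth and water loss.

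With the replicate block more genes were lower than higher, 76.5% of calls. With median-ratio scaling added 45.42% were lower, below the share that the rule fixed before took as a sign of scaling. This scaling brings the median gene near 0 and thereby sets the share, a point that rule did not weigh. Scaling between libraries and a broad fall under shear therefore cannot be told apart by it. The median gene stood at -0.08, -0.07 and -0.22 log2 in pairs 1 to 3. In pairs 1 and 2 more genes were higher by 1 log2 than lower (299 against 199, 171 against 67), and in pair 3 fewer (94 against 242). With pair 3 left out, 63.1% of calls with the block were lower. Transcript length gave a Spearman correlation of 0.00687 with the log2 difference (0.0704, 0.0753 and -0.133 in the 3 pairs), and genes with the nonamer of short-lived transcripts differed from matched genes by 0.01219 log2, which decides neither.

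Of the genes risen 2-fold or more, 6.329% had a match to the B2 repeat, against 13.92% of matched genes, which argues against reads of B2 repeat RNA. Another of these genes lay within 10 kb for 4 of them (Hspe1 with Hspd1, and Hspa1l with Hspa1a), and 2.71% of random sets had as many, as neighbouring genes rising together would give. Hspe1, Hspd1 and Hspa1a belong to the heat shock list, and the random sets were not matched for such genes. The count therefore cannot be told apart from the rise of heat shock genes. Hspa1l is a close relative of Hspa1a, so shared reads stay open for that pair.

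The 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 93 genes higher, 94 lower, 85 higher by 2-fold and 53 lower by 2-fold, and the highest other 0 each time by limma (1 of 10 splits as large); at an unadjusted p under 0.05 the real split gave 1969 genes and others up to 1810. For gene lists the real value was 7, the highest other 15, and 8 of the 10 splits gave as many. The 3 other splits that part all pairs gave 0 genes with the block, against 3581, and 4, 8 and 6 lists. Each of these turns a pair round, and every other split mixes FSS and static libraries. A difference between FSS and static then adds to the spread, so counts of 0 genes would follow whatever its cause.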
